A study of Mus musculus with 4 samples.

How the data were processed

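The series holds 4 RNA-seq libraries of cultured mouse forelimbs, 2 from control medium and 2 from medium with cyclopamine, from wild-type Swiss Webster embryos at E10.25. Per the labels' protocols, limb buds were taken for TRIzol extraction of RNA at the end of culture, and libraries were made with the platform maker's standard SOLiD protocols. The dose, the vehicle, the length of culture and the number of limbs per library are not given in the sources used here. TopHat2 2.0.9, Bowtie, SAMtools, HTSeq 0.5.4p5, edgeR 3.4.2 and the mm10 build are listed in the submitters' processing notes, with no role or order. The gene annotation, the handling of strand and the treatment of reads that map to several places are not given in the sources used here. Genes that share sequence with close copies or overlap another gene may therefore have uncertain values. Exons of 10 of the 37 called genes found in the GENCODE vM21 annotation overlap another gene's exons, 8 of them on the opposite strand.

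The deposited expression table gives a normalized signal per gene and library, which the authors scaled to counts per 1000000 (CPM) of an effective library size. The deposited signal of a library sums to between 973185 and 1022612. Every deposited CPM value is a whole multiple of what a single read is worth in its library (100% of values in each library, within 0.01 of a whole read), so the reads could be recovered. A read is worth 0.103 CPM in control 1, 0.0735 in control 2, 0.0789 in cyclopamine 1 and 0.081 in cyclopamine 2. TMM factors recomputed with edgeR from the recovered reads equal the ratios of effective to actual library size, at 0.991, 1.00, 0.978 and 1.03. This scaling assumes that most genes do not differ between libraries. The authors' deposited table of the comparison gives a log2 fold change, a mean log2 CPM, a p-value and a false discovery rate per gene, with the test not stated. edgeR's exact test on the recovered reads of all 17568 genes without a filter gave the same 80 genes, with log2 fold changes within 0.000467 of the authors' deposited values.

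The floor of detection was set at 3 reads, which is 0.31 CPM in control 1, 0.22 in control 2, 0.237 in cyclopamine 1 and 0.243 in cyclopamine 2. Floors and counting intervals cover counting error only, because reads without molecular identifiers are not independent molecules. The 10 most abundant genes took 5.59%, 4.76%, 5.59% and 5.46% of reads in the same order of libraries, and Rn45s, a ribosomal RNA precursor, took 0.995%, 0.868%, 1.06% and 1.36%. No pair of libraries agreed within sampling noise, with a chi-square per degree of freedom of 8.53 or more. The table holds 0 mitochondrially encoded genes, so that list was not tested. It also holds 25 gene names that a spreadsheet had turned into dates, of which 0 were called.

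Genes were compared with limma 3.58.1 in R 4.3.3 on log2(CPM + 0.5), with an intensity trend and no other covariate, for genes with a mean of at least 1 CPM over the 4 libraries. This is the form fixed for normalized values; a count test would have been used for whole counts. Fold changes are on the log2(CPM + 0.5) scale, which understates the change of genes near the floor. P-values are two-sided and Benjamini-Hochberg adjusted over the 13568 genes tested, with a threshold of 0.05. With 2 libraries per group, an exact permutation of labels cannot reach 0.05, so the test relies on the spread shared across genes. The labels call the libraries biological replicates and say nothing of how many embryos or cultures each holds.

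Before the data were examined, 30 gene lists were fixed, and ribosomal protein and histone genes were added by name prefix, giving 32 tested lists. Older symbols were matched through a RefSeq table of synonyms. Lists were tested with camera at a preset correlation of 0.01, adjusted over lists, then with camera at a correlation estimated from 2 residual degrees of freedom, and with fry. Fry, which asks whether a list's genes move on balance in a single direction, called 0 lists, and its mixed form called 2, posterior limb genes (adjusted p = 0.0433) and WNT response genes (adjusted p = 0.0132). The genes named were fixed by a rule as well: the 4 Hedgehog targets, up to 12 rises and 12 falls of largest size among named genes past the threshold with both cyclopamine libraries on the same side of both controls, up to 4 members of each list with the smallest p, and the 10 largest folds in each direction in the authors' deposited table. Further genes are named where a count of 5 or fewer, or a list's members past the threshold, called for it, and these were chosen after their values were seen. The rule passed over 1 called gene model without a name, and some genes that it covers are not reported here.

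Alternatives were edgeR 4.0.16 (quasi-likelihood) on recovered reads, other scalings, filters, pseudocounts, variance models and thresholds, a block for the replicate number, and leaving out each library in turn. DESeq2 1.42.0, the exact test, plain CPM, the block in edgeR and the estimated correlation were added after seeing the data. The procedure was tested on simulated negative binomial counts for the same 13568 genes and library sizes, with 200 genes changed in each of 10 simulations. It found 20.9% of genes changed 1.5-fold, 65.1% of those changed 2-fold and 94.2% of those changed 4-fold, and 8.68% of its calls were false, above the nominal share. Coordinates are from GENCODE vM21 in mm10 coordinates, where 161 of 164 symbols looked up had a single match.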

Results

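Gene expression was measured by RNA sequencing in forelimbs of wild-type Swiss Webster mouse embryos at E10.25, staged at 31 to 34 somites, that had been cultured in control medium or in medium with cyclopamine. Cyclopamine is a plant alkaloid that inhibits Smoothened, the membrane protein that carries the Hedgehog signal into the cell. Each condition had 2 libraries, described by the submitters as biological replicates, and the platform was SOLiD, a ligation-based short-read sequencer. The deposited values correspond to 9779589 gene-assigned reads in control 1, 13555492 in control 2, 12962633 in cyclopamine 1 and 12010965 in cyclopamine 2. The table listed 17568 genes, of which 13568 reached a mean of 1 CPM (normalized counts per 1000000 reads) and were tested. Pearson's r of the log2 values across genes was 0.983 between the control libraries and 0.982 between the cyclopamine libraries, and it ranged from 0.978 to 0.986 between conditions.

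The comparison asked which forelimb transcripts differ when Hedgehog signalling is inhibited in culture. The direct transcriptional targets of the pathway were lower in cyclopamine. Gli1, which encodes a transcription factor induced by the pathway, fell from 56.5 ± 0.343 CPM (SD, n = 2) to 6.37 ± 2.37 CPM (SD, n = 2), a log2 fold change of -3.10 (SE 0.23). Ptch1, which encodes a Hedgehog receptor, fell by 1.44 (SE 0.19) on the log2 scale. In the other direction, Mt1 and Mt2, which encode metal-binding metallothioneins, rose by 3.13 (SE 0.23) and 3.28 (SE 0.36). Across all genes tested, limma placed 38 past an adjusted p of 0.05, of which 6 rose and 32 fell. At an unadjusted p under 0.05 the directions were closer to balance, with 412 genes higher and 377 lower.

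The 4 Hedgehog target genes were the same in direction in every library pair. Ptch1 measured 116 and 107 CPM in the controls and 51.3 and 32.2 CPM in cyclopamine. Hhip, which encodes a Hedgehog-binding inhibitor, measured 8.46 and 9.70 CPM against 5.05 and 3.4 CPM. Adjusted p in limma was 4.32e-06 for Gli1 and 0.00216 for Ptch1. Hhip did not pass over all genes (log2 fold change -1.04, SE 0.29, adjusted p = 0.289). Adjusted over the list alone, all 4 genes fell, with Hhip at 0.0024. As a set the targets had a median log2 fold change of -2.26 (camera, adjusted p = 1.57e-19), which became an adjusted p = 0.252 with an estimated correlation. In mm10 the annotated genes lie at chromosome 10, 127329882 to 127341974 (Gli1), chromosome 13, 63508328 to 63573598 (Ptch1) and chromosome 8, 79965851 to 80058006 (Hhip). Exons of Gli1 and Hhip overlap annotated genes on the opposite strand, and whether reads were counted by strand is not given in the sources used here.

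**Figure D1:**
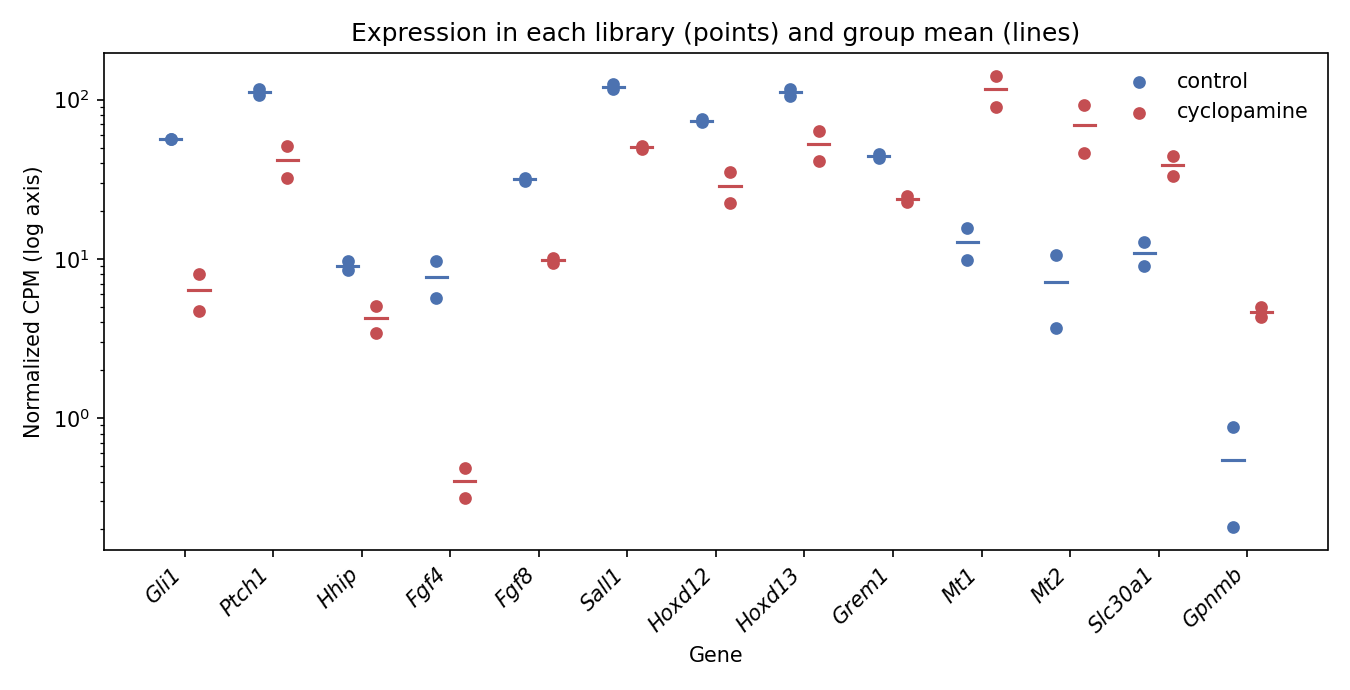
Normalized CPM on a log axis for 13 genes in the 2 control and 2 cyclopamine libraries, with points for libraries and short lines for group means. Gli1 lies at 56.2 and 56.7 CPM in the controls and at 8.05 and 4.70 CPM in cyclopamine, and Mt1 at 15.7 and 9.84 CPM against 142 and 90.4 CPM.

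The 18 tested components of the Hedgehog pathway, from ligand to kinases, included 0 genes past the threshold in limma, and 0 when adjusted over the list alone. Their median log2 fold change was -0.01 (camera, adjusted p = 0.682, and adjusted p = 0.908 with an estimated correlation), and it ran from -0.20 without cyclopamine 2 to 0.11 without cyclopamine 1. Shh, the limb's Hedgehog ligand, measured 7.84 and 14.5 CPM in the controls and 6.07 and 8.02 CPM in cyclopamine (log2 fold change -0.58, SE 0.29). Smo, which encodes Smoothened, measured 176 and 177 CPM against 163 and 164 CPM.

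The rises included genes of metal handling. Mt1 reached 116 ± 36.1 CPM (SD, n = 2) from 12.8 ± 4.13 CPM (SD, n = 2), with a limma adjusted p = 4.32e-06. Mt2 measured 10.6 and 3.67 CPM in the controls and 92.8 and 46.2 CPM in cyclopamine (adjusted p = 0.000496). Slc30a1, which encodes a zinc exporter of the plasma membrane, rose from 10.9 to 38.6 CPM, by 1.79 (SE 0.22) on the log2 scale (adjusted p = 0.00119). The remaining rises were Gpnmb (2.37, SE 0.43), which encodes a transmembrane glycoprotein, Fibin (1.01, SE 0.20) and Kif1a (0.99, SE 0.18), which encodes a kinesin motor. Mt2 and Mt1 are neighbours on chromosome 8, at 94172664 to 94173568 and 94179082 to 94180327. Fibin lost its call without control 1 or without cyclopamine 2 (largest adjusted p = 0.151), and Kif1a without control 2 (adjusted p = 0.14).

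Among the falls of largest size were Fgf4 (-3.15, SE 0.40), a growth factor of the apical ectodermal ridge, and Mamdc2 (-2.33, SE 0.31). The others in this group were genes known from neural tissue: Zic1 (-3.25, SE 0.58), Ina, Myt1 (-2.57, SE 0.49), Pou3f2 (-2.42, SE 0.48), Elavl3 (-2.24, SE 0.38), Thy1 (-2.14, SE 0.40), Stmn2 (-2.04, SE 0.33) and Tubb3 (-1.82, SE 0.28). Ina, a neuronal intermediate filament gene, had 0 reads in both cyclopamine libraries and 75 control reads, of which 59 came from control 2. Against the pooled controls it was at least 26.8-fold lower, taking 3 reads over the group, or 0.12 CPM, as the floor. This bound covers counting error only, not the difference between the control libraries. Control 2 held more of several of these transcripts than control 1, with Zic1 at 15.9 against 6.50 CPM and Elavl3 at 9.33 against 4.85 CPM. Without control 2 the calls of Zic1 (adjusted p = 0.14), Elavl3 (0.208), Pou3f2 (0.434) and Thy1 ended, and Ina and Myt1 fell under the expression filter. Thy1 lost its call without control 1 as well (largest adjusted p = 0.13).

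Of the 38 genes, 16 kept their call in each of the 4 fits that left out a library, among them Gli1, Ptch1, Mt1, Mt2, Slc30a1, Fgf4, Fgf8, Sall1, Hoxd12 and Hoxd13. The authors' deposited table marks 80 genes at a false discovery rate under 0.05, 19 higher and 61 lower, and these include all 38. Its log2 fold change is -3.14 for Gli1, 3.19 for Mt1, 3.30 for Mt2 and -4.24 for Fgf4. Further large changes in the authors' deposited table are falls of Neurod4 (-7.10), Slc17a6 (-6.76), Olig3 (-6.54), Nhlh1 (-5.17), Scg3 (-4.62), Rfx4 (-4.52), Robo3 (-4.44) and Msx3 (-4.39). On the side of rises the authors' deposited table has C3 (3.83), Snord55 (3.59), Rgs18 (3.35), Parp14 (3.11), Gpnmb (2.97), Gpr50 (2.58), Lilrb4 (2.34) and Hemgn (2.09). Refitted here, Rfx4 (-2.49, SE 0.54, limma adjusted p = 0.0877), Robo3 (-2.38), Rgs18 (1.95), Parp14 (1.94), Lilrb4 (1.75), Hemgn (1.70) and Gpr50 (1.62) did not pass. C3 measured 27.1 CPM in cyclopamine 2 and between 0.735 and 1.24 CPM in the other libraries, and it did not pass (2.15, SE 0.83, adjusted p = 0.677). Neurod4, Slc17a6 and Olig3 had 34, 26 and 23 control reads and 0 reads in cyclopamine. Against the pooled controls they were at least 12.2-fold, 9.30-fold and 8.23-fold lower, with the same floor over the group and for counting error only. Neurod4, Slc17a6, Olig3, Nhlh1, Scg3 and Msx3 lay under the expression filter and were not tested in limma. The count of 38 depended on the model. Limma called 0 genes without an intensity trend (837 at an unadjusted p under 0.05) and 2 without the expression filter. The quasi-likelihood test of edgeR on recovered reads called 43. With a block for the replicate number, which the labels tie to no litter or day, limma called 351, of which 186 rose and 165 fell. These included all 38. The balance of rises and falls depended on the libraries included: 40 rose and 39 fell without control 1, 24 and 19 without control 2, 68 and 54 without cyclopamine 1, and 28 and 56 without cyclopamine 2.

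The list of posterior limb genes, drawn up as downstream of Shh, was lower in cyclopamine as a set, with 13 genes lower and 4 higher. Of the 17 tested, 6 fell over all genes and 9 fell when adjusted over the list alone. Sall1, a zinc finger transcription factor gene, fell from 120 to 50.1 CPM (-1.25, SE 0.15, limma adjusted p = 0.000921). Hoxd12 (-1.38, SE 0.19), Hoxd13 (-1.11, SE 0.19) and Hoxd11 (-0.92, SE 0.18), homeobox genes that pattern the distal and posterior limb, fell, as did Fgf4 and the BMP antagonist gene Grem1 (-0.88, SE 0.17). Hand2, which marks posterior mesenchyme, fell only when adjusted over the list alone (-0.53, SE 0.15), whereas Tbx2 and Tbx3 had log2 fold changes of 0.04 and 0.15. The set had a median of -0.40 (camera, adjusted p = 4.37e-14), with an adjusted p = 0.252 with an estimated correlation. The median was -0.21 without control 1. Hoxd11 lost its call without control 1 or without cyclopamine 2 (largest adjusted p = 0.148). Grem1 kept its call only without cyclopamine 2 (largest adjusted p = 0.144 in the other fits).

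**Figure D2:**
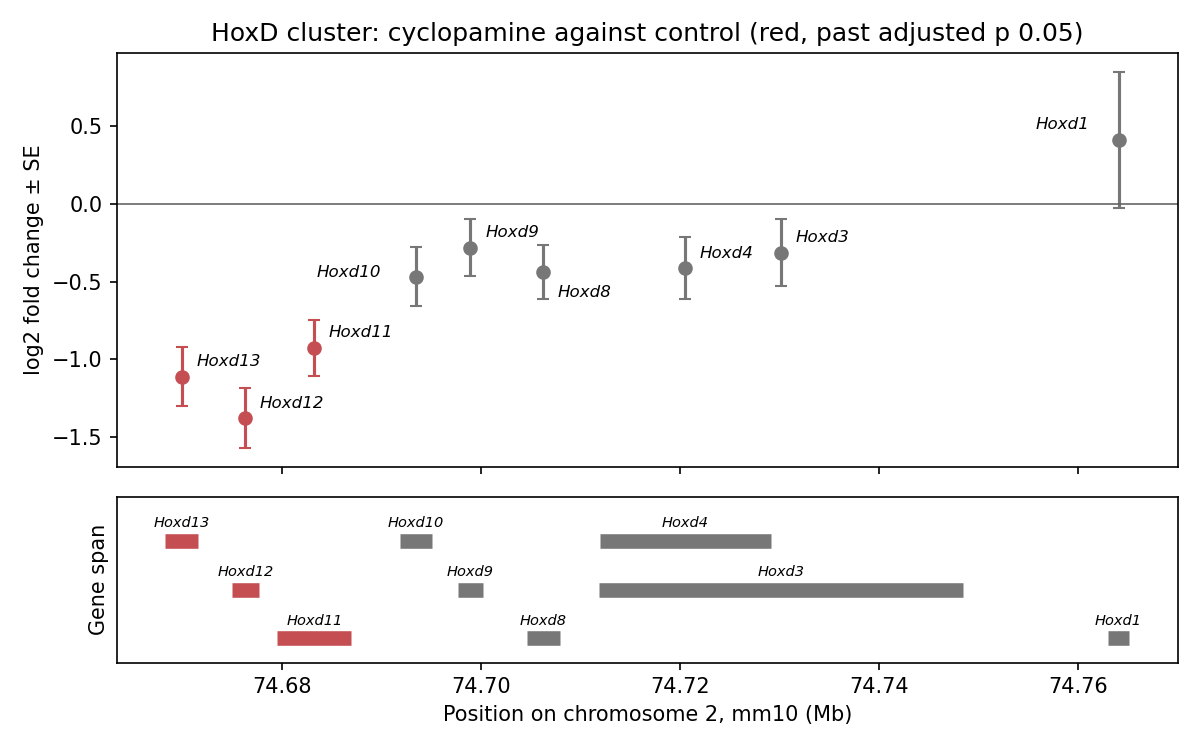
Log2 fold change with its SE for the 9 genes of the HoxD cluster above their positions on chromosome 2 (mm10, in Mb), with genes past the limma threshold in red. Hoxd13, Hoxd12 and Hoxd11 lie at -1.11, -1.38 and -0.92, and the other 6 genes lie between -0.47 and 0.41.

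Anterior limb genes lay slightly above control, while the proximal list depended on the libraries included. In the anterior list, 12 of 13 genes were higher, 0 passed over all genes, and Pax1, a paired box gene, rose when adjusted over the list alone (0.97, SE 0.26). Tbx18 (0.35, SE 0.15) did not pass. The anterior set had a median of 0.21 (camera, adjusted p = 0.000346, and adjusted p = 0.312 with an estimated correlation). The proximal list had 8 of 13 genes higher, 0 past either threshold and a median of 0.16 (camera, adjusted p = 0.0173), with an adjusted p = 0.581 with an estimated correlation. Shox2, needed for the proximal limb skeleton, had a log2 fold change of 0.42 (SE 0.16) and Irx5 of 0.63 (SE 0.31). The proximal call ended without control 2 or without cyclopamine 1 (largest adjusted p = 0.778), and the median ran from -0.04 without control 2 to 0.36 without control 1.

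Distal limb genes had a median log2 fold change of -0.46 over 14 members (camera, adjusted p = 1.73e-07, and adjusted p = 0.252 with an estimated correlation). Without control 2 the median was -0.25. Over all genes 1 member, Hoxd13, fell; adjusted over the list alone, 7 fell and 1, Msx2, rose (0.52, SE 0.20). The 7 included Tfap2c (-0.82, SE 0.18), Lmo2 (-0.84, SE 0.20), Mycn (-0.55, SE 0.15) and Hoxa13 (-1.03, SE 0.28). Among 16 limb mesenchyme markers, Sall3 fell (-0.94, SE 0.17, limma adjusted p = 0.0272), and adjusted over the list alone Fgf10 (-0.60, SE 0.16) and Sall4 (-0.58, SE 0.16) fell too. That set had a median of -0.08 (camera, adjusted p = 0.0329, and adjusted p = 0.39 with an estimated correlation), and its call ended without control 1 or without cyclopamine 2 (largest adjusted p = 0.501), with medians from -0.20 to 0.01. Sall3 lost its call without control 2 (adjusted p = 0.0771).

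In the apical ectodermal ridge and limb ectoderm list, 2 of 16 genes fell over all genes. Fgf8, the growth factor made along the whole ridge, went from 31.6 ± 1.04 CPM (SD, n = 2) to 9.79 ± 0.55 CPM (SD, n = 2), a log2 fold change of -1.64 (SE 0.20, limma adjusted p = 0.000973). Fgf4 went from 5.67 and 9.70 CPM to 0.316 and 0.486 CPM, the latter resting on 4 and 6 reads (adjusted p = 0.00128). Wnt7a, a dorsal ectoderm gene, fell when adjusted over the list alone (-1.06, SE 0.27). The median was -0.23 (camera, adjusted p = 5.88e-05, and adjusted p = 0.252 with an estimated correlation), and -0.15 without control 1. All 12 FGF response genes were lower, with a median of -0.27 (camera, adjusted p = 4.45e-08, and adjusted p = 0.252 with an estimated correlation). Of these, 0 passed over all genes and 2 fell when adjusted over the list alone, Ccnd1 (-0.70, SE 0.16), a cyclin gene, and Spry4 (-0.62, SE 0.15), a feedback inhibitor of FGF signalling.

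Cell cycle lists were lower as sets. All 19 G2/M genes were lower, with a median of -0.30 (camera, adjusted p = 2.75e-11, and adjusted p = 0.346 with an estimated correlation). Over all genes 0 of them passed, and adjusted over the list alone Plk1 (-0.57, SE 0.15) and Aurkb (-0.54, SE 0.15), mitotic kinase genes, fell. Among 22 genes of G1/S and DNA replication 6 were higher and 16 lower, and the median was -0.15 (camera, adjusted p = 2.46e-05, and adjusted p = 0.346 with an estimated correlation). Without control 1 that median was -0.25 and without control 2 it was -0.09. Both lists were also called between control 1 with cyclopamine 2 and the remaining libraries (adjusted p of 0.0014 for G2/M and 0.0239 for G1/S). Again 0 passed over all genes, while Cdk6 (-0.96, SE 0.20), Ccnd1 and Mycn fell when adjusted over the list alone. The 12 tested histone genes had a median of 0.11 (camera, adjusted p = 0.446, and adjusted p = 0.676 with an estimated correlation), or -0.20 without control 2, and the 89 ribosomal protein genes had a median of 0.01 (0.759 and 0.955 by the same tests), with 0 genes of either list past a threshold. In the fits that left out a library the ribosomal list was called all 4 times, in both directions, with medians from -0.15 to 0.19 (largest adjusted p = 0.00261). It was also called between the replicate numbers (adjusted p = 7.08e-31).

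Genes of cholesterol synthesis and other targets of the sterol-responsive factor SREBP2 lay above control in 25 of 25 cases. None of them passed over all genes in limma (0 of 25), and 18 rose when adjusted over the list alone. Insig1, a sterol-responsive regulator, measured 110 and 180 CPM in the controls and 232 and 225 CPM in cyclopamine (0.70, SE 0.19), and the enzyme gene Nsdhl measured 85.8 and 143 CPM against 174 and 183 CPM. The median was 0.52 (camera, adjusted p = 5.1e-22, and adjusted p = 0.346 with an estimated correlation). Control 1 lay below control 2 for these genes, and without control 1 the median was 0.22 (adjusted p = 0.000107), against 0.88 without control 2. The list was also called in both divisions of the libraries that do not follow treatment (adjusted p of 8.9e-06 and 7.34e-07).

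Stress-related lists were higher as sets, and they differed between the control libraries. Immediate early genes had a median of 0.31 over 18 genes (camera, adjusted p = 0.000343, and adjusted p = 0.578 with an estimated correlation), with Egr1 (0.78, SE 0.20) and Fos (1.45, SE 0.38) rising when adjusted over the list alone. Unfolded protein and amino acid stress genes had a median of 0.31 over 18 genes (adjusted p = 0.000131, and adjusted p = 0.393 with an estimated correlation), with Trib3 at 0.77 (SE 0.23) and 0 past either threshold. Heat shock genes had a median of 0.20 over 11 genes (adjusted p = 0.00134, and adjusted p = 0.569 with an estimated correlation). Hspa1b and Hspa1a, near-identical copies whose reads cannot be assigned with certainty, rose when adjusted over the list alone. Hspa1b measured 23.4 and 0.735 CPM in the controls and 57.4 and 22.8 CPM in cyclopamine. Without control 2 all 3 calls ended, at camera adjusted p of 0.901, 0.156 and 0.169, and without cyclopamine 1 the first 2 ended, at 0.333 and 0.231. In the fits that left out a library the medians ran from 0.02 to 0.55 for immediate early genes, 0.07 to 0.37 for unfolded protein genes and 0.08 to 0.45 for heat shock genes. Among 19 genes of the p53 response and apoptosis, 0 passed over all genes, and adjusted over the list alone Trp53inp1 rose (0.70, SE 0.18) and Eda2r fell (-0.83, SE 0.21). The list had a median of -0.07 and a mean of 0.07 (camera, adjusted p = 0.682, and adjusted p = 0.908 with an estimated correlation), and it was called without cyclopamine 2 (median 0.11, adjusted p = 0.00891). The 25 hypoxia response genes had a median of -0.06 (0.446 and 0.676 by the same tests), with 0 past either threshold and medians from -0.13 to 0.09 in the fits that left out a library.

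Other signalling lists held few changes. In the BMP list of 18 genes, Grem1 fell and the median was 0.22 (camera, adjusted p = 0.0943, and adjusted p = 0.676 with an estimated correlation). That list was called without control 1 (median 0.38, adjusted p = 5.78e-05) and without cyclopamine 2 (adjusted p = 0.0451), and its median was -0.00027 without control 2. In the WNT list of 12 genes, Apcdd1, an inhibitor of WNT signalling, fell when adjusted over the list alone (-0.67, SE 0.15), and the median was -0.11 (0.124 and 0.572 by the same tests). The retinoic acid list of 14 genes had 0 past either threshold and a median of 0.11 (0.278 and 0.712), with a call without control 1 (median 0.19, adjusted p = 0.0457) and a median of -0.03 without control 2. Of 13 NOTCH pathway genes, Heyl fell when adjusted over the list alone (-1.18, SE 0.34), and the median was -0.03 (0.0329 and 0.346), a call that held only without control 2 among the fits leaving out a library (largest adjusted p = 0.209), where the median ran from -0.21 to -0.06. The 14 cartilage condensation genes had 0 past either threshold and a median of -0.16 (0.262 and 0.578), with Col2a1, the main cartilage collagen gene, at 0.41 (SE 0.15). The cartilage list was called without control 2 (median -0.43, adjusted p = 0.00269), and its median was -0.01 without control 1.

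Neural and Schwann cell markers were lower, with 3 of 12 tested genes falling over all genes and 7 when adjusted over the list alone. Tubb3, which encodes a neuronal tubulin, measured 14.4 and 20.4 CPM in the controls and 3.47 and 5.83 CPM in cyclopamine (limma adjusted p = 0.0112). Stmn2 measured 8.25 and 8.45 CPM against 2.21 and 1.22 CPM, and Elavl3 fell from 4.85 and 9.33 CPM to 1.10 and 0.972 CPM. The median was -1.08 (camera, adjusted p = 5.91e-15, and adjusted p = 0.252 with an estimated correlation). Elavl3 lost its call without control 2 (adjusted p = 0.208).

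Markers of blood and vessels were higher as sets. Erythroid markers had a median of 0.65 over 12 genes (camera, adjusted p = 1.17e-05, and adjusted p = 0.346 with an estimated correlation). The embryonic globin genes Hba-x (0.95, SE 0.30) and Hbb-y (0.90, SE 0.28) rose when adjusted over the list alone, and 0 passed over all genes. Hba-x measured 524 and 234 CPM in the controls and 874 and 523 CPM in cyclopamine. Endothelial markers had a median of 0.24 over 16 genes (adjusted p = 0.000346, and adjusted p = 0.333 with an estimated correlation), with Eng at 0.60 (SE 0.20) and 0 past either threshold. The erythroid median was 1.13 without control 1 and 0.14 without control 2. Without control 2 the erythroid and endothelial calls ended, at camera adjusted p of 0.156 and 0.102, and the endothelial median was 0.15. Macrophage and leukocyte markers had 0 of 11 past either threshold and a median of -0.04 with a mean of 0.04 (0.763 and 0.908 by the same tests), with medians from -0.14 to 0.41 in the fits that left out a library.

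Markers of other tissues of the limb and trunk held no call over all genes. Myogenic markers had 0 of 10 past either threshold and a median of 0.24 (camera, adjusted p = 0.0355, and adjusted p = 0.572 with an estimated correlation), and the call ended without control 1 or without cyclopamine 2 (largest adjusted p = 0.973), with medians from -0.10 without cyclopamine 2 to 0.56 without control 2. Ectoderm and epithelium markers had a median of 0.16 over 16 genes (adjusted p = 0.0164, and adjusted p = 0.581 with an estimated correlation), and Krt15, a keratin gene, rose when adjusted over the list alone (1.30, SE 0.31). That set's call ended without control 2 or without cyclopamine 1 (largest adjusted p = 0.969), and its median was -0.16 without control 2 and 0.51 without control 1. Somite and trunk markers had a median of 0.16 over 13 genes (0.295 and 0.578 by the same tests), with Pax1 rising and Foxf1 (-1.47, SE 0.44) falling when adjusted over the list alone. They were called without control 1 (median 0.26, adjusted p = 0.037), and the median was -0.13 without control 2.

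Among 5 sex-linked genes, the Y-linked Kdm5d fell over all genes, from 61.0 and 60.0 CPM to 37.9 and 26.8 CPM (-0.91, SE 0.18, limma adjusted p = 0.0475). Adjusted over the list alone, all 4 Y-linked genes fell and Xist, the transcript of the inactive X chromosome, rose (0.89, SE 0.31). Xist measured 532 and 1026 CPM in the controls and 993 and 1900 CPM in cyclopamine, so cyclopamine 1 lay below control 2. It did not pass over all genes (limma adjusted p = 0.542). The median of the list was -0.80 (camera, adjusted p = 1.38e-05, and adjusted p = 0.312 with an estimated correlation). Without cyclopamine 2 the median was -0.51. Kdm5d kept its call only without cyclopamine 1 (largest adjusted p = 0.225 in the other fits).

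Over the 32 lists tested, camera with a preset correlation called 21, 10 higher and 11 lower, and with an estimated correlation it called 0 (6 at an unadjusted p under 0.05). The other 2 ways of dividing the 4 libraries into equal groups gave 14 and 6 called lists with the preset correlation. A list's call alone therefore does not separate treatment from differences between libraries. With a block for the replicate number, which the labels tie to no litter or day, camera at the preset correlation called 22 lists. These included all 21. Their adjusted p in that fit was 1.28e-12 for heat shock genes and 3.59e-12 for erythroid markers. The Hedgehog target, distal limb, apical ridge, FGF response, neural, anterior limb and sex-linked sets were called in all 4 fits that left out a library and in neither of the other divisions. The posterior limb, proximal limb, cell cycle, cholesterol, immediate early, unfolded protein, heat shock, erythroid, myogenic and ectoderm sets were called in at least 1 of the other divisions as well. Of the 11 lists not called, 6 were called in at least 1 fit that left out a library. The Hedgehog component, BMP, retinoic acid, p53, hypoxia, macrophage and ribosomal sets, 7 of these 11, were called in at least 1 of the other divisions.

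**Figure D3:**
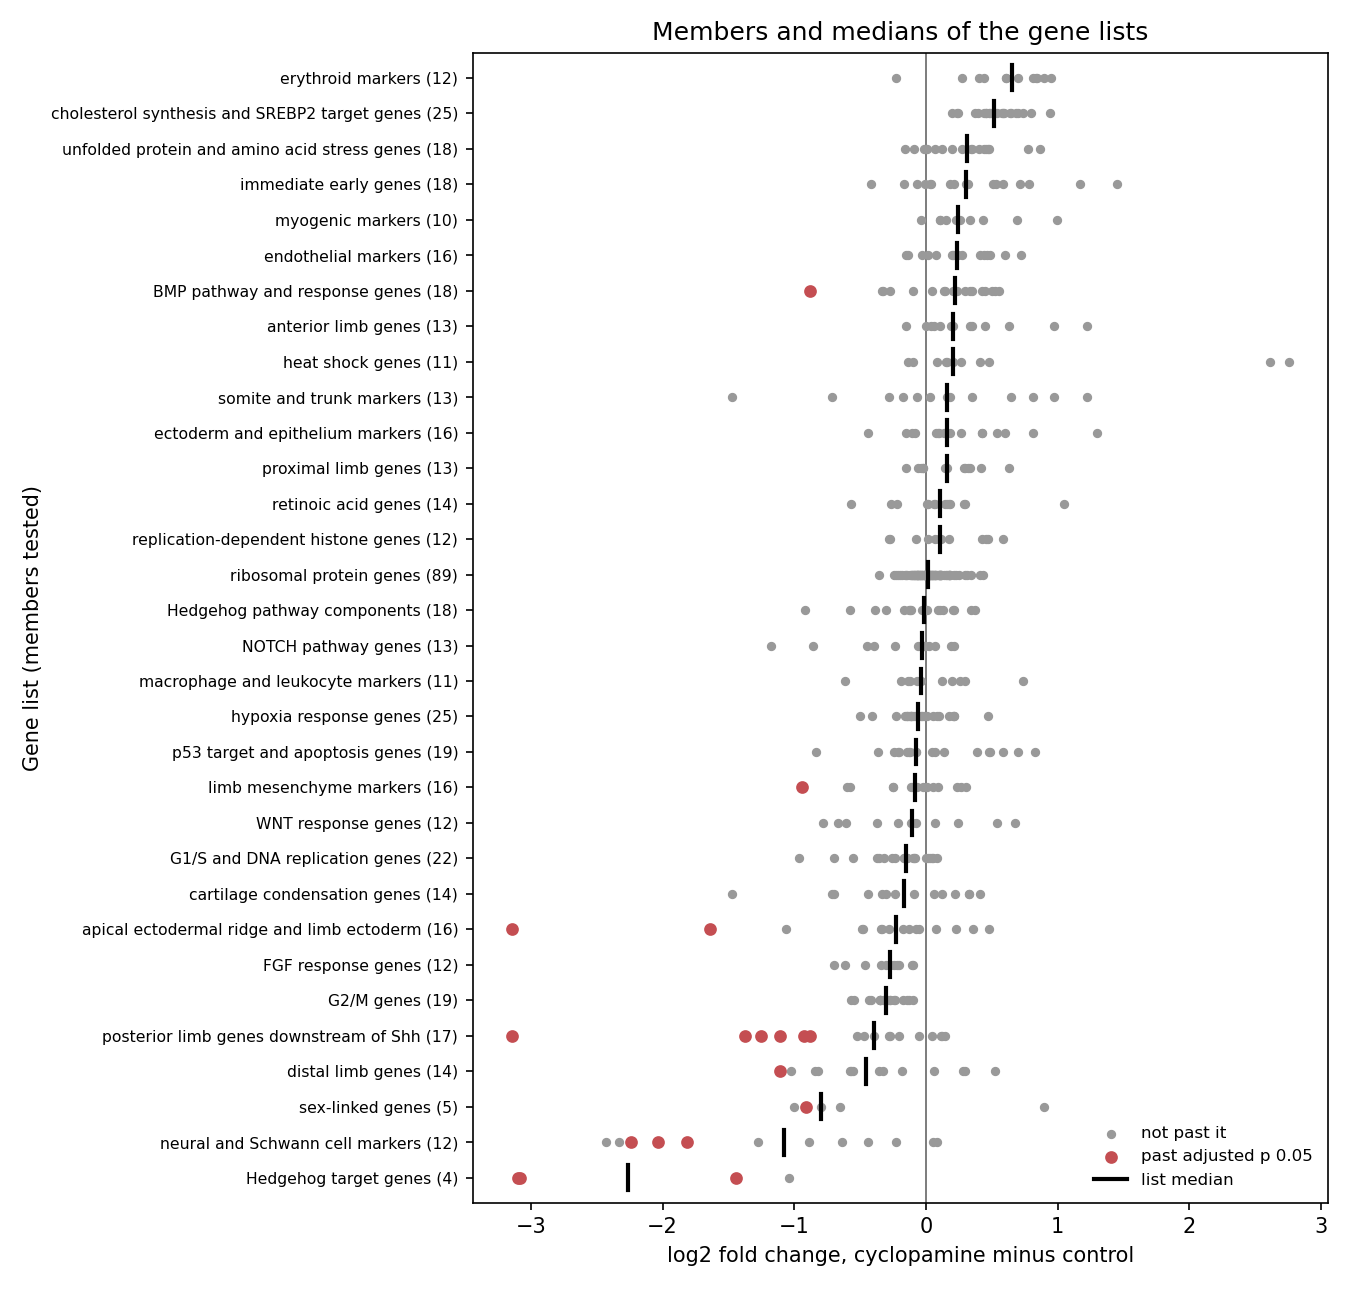
Log2 fold changes of the tested members (points) and the median (black line) of 32 gene lists, with members past the limma threshold in red and the number tested in brackets. The Hedgehog target median lies at -2.26, the neural median at -1.08 and the cholesterol synthesis median at 0.52.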

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

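DESeq2, the exact test, plain CPM, edgeR with the block and the estimated correlation were chosen after seeing the data; the other alternatives were fixed before. The 38 calls became 25 under quantile normalization, 20 with plain CPM, 2 without the expression filter (with 17568 genes tested) and 0 without the intensity trend in limma (837 at an unadjusted p under 0.05; edgeR 43), and 80 in the exact test; the cause was not tested for the scalings, the trend and the exact test. Leaving out a library, which assumes that the lone library varies like the other group, gave 43 to 122 calls. Other settings gave 27 to 56 calls. The libraries share replicate numbers that the labels tie to no litter or day: deviations from the group means correlated at r = 0.274 across genes, the first principal component (40.4% of variance) parted the numbers, and a replicate block gave 351 calls in limma (186 higher and 165 lower) and 372 in edgeR, each including all 38, and called the BMP list (adjusted p = 0.0354 and 0.0377). Dividing the libraries by number without a block called 0 genes in limma and edgeR (1573 at an unadjusted p under 0.05 in limma), and the remaining division 0 (109); 3 divisions are too few for a share under 0.05. With the preset correlation, the Hedgehog target list was called in every setting run, with medians between -1.87 and -2.50, and 16 to 22 lists were called. With an estimated correlation its adjusted p was 0.252 and 0 lists were called; that setting changes both the correlation and the degrees of freedom, and these were not tested apart. For the 26 called genes among those named by the rule, 358 of 459 alternative values kept their call, 101 lost it and 0 reversed; 0 of the 38 genes were called in every setting. Depth limits genes near the floors of 0.22 to 0.31 CPM, below which a value cannot be told from 0.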

Other observations

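The lists tested here were drawn up after the gene calls had been seen; the tests on neural tissue, Y-linked genes and the HoxD cluster were chosen after their own results were seen, and the others before.

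Megakaryocyte and platelet genes were higher in cyclopamine as a list. Rises of Pf4, Rgs18 and Hemgn, genes of megakaryocytes and other blood cells, prompted it. Of its tested members 9 of 9 were higher and 0 passed over all genes in limma (camera, adjusted p = 8.79e-10, and p = 0.0533 with an estimated correlation). Both p-values include Pf4, Rgs18 and Hemgn, so they partly restate the rises that prompted the list. The 6 members other than these had a median log2 fold change of 0.70, consistent with more megakaryocytes or platelets in the cyclopamine libraries (median 0.703). Itga2b, an integrin gene of platelets, measured 3.82 and 3.53 CPM in the controls and 6.63 and 9.80 CPM in cyclopamine. Erythroid markers had a median of 0.65 and macrophage and leukocyte markers of -0.04, so a rise limited to megakaryocytes and platelets was not shown. Interferon response genes were higher in 11 of 11 cases beside Parp14, with a median of 0.371 and 0 past the threshold over all genes. Camera gave an adjusted p = 3.77e-05 over the lists drawn up later, and p = 0.0677 with an estimated correlation. The median lay between the bounds set beforehand, so an interferon response stays open. Lysosome genes were higher in 17 of 20 cases beside Gpnmb, with a median of 0.2 and 0 past the threshold over all genes (camera p = 7.4e-05, and p = 0.214 with an estimated correlation), so a general rise of lysosome genes stays open.

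Across the 9 genes of the HoxD cluster, which are not independent replicates, position from Hoxd1 to Hoxd13 and log2 fold change had a Spearman correlation of -0.883 and a Pearson correlation of -0.894. This was the only relation of its kind computed, and it was computed after the falls of Hoxd11, Hoxd12 and Hoxd13 had been seen, so it does not test for a gradient. The values are -1.376 for Hoxd12 and -1.111 for Hoxd13. Exons of Hoxd3, Hoxd4, Hoxd10 and Hoxd11 overlap other annotated genes, so their reads are less certain.

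Sums of neural genes were lower in both cyclopamine libraries. Summed CPM of 14 neural tube progenitor genes was 16.6 in control 1, 38.1 in control 2, 3.71 in cyclopamine 1 and 3.73 in cyclopamine 2, and sums of 21 neuron genes were 113, 157, 65.2 and 61.4. A shift from ventral to dorsal identity in neural tissue stays open. The sum of 10 dorsal genes had a log2 ratio of -2.56, but most of it came from Zic1, Olig3 and Msx3, whose falls prompted the test. The other 7 had sums of 3.1, 4.7, 2.84 and 1.38 CPM (log2 ratio -0.929, from 94 and 53 reads), too few to decide. Sums of 7 ventral genes were 4.54, 3.53, 2.13 and 4.05 CPM (log2 ratio -0.359, counting interval -0.815 to 0.0934). Neither a rise of dorsal genes nor a clear fall of ventral genes was seen at these low values. Differing amounts of neural tube carried over in dissection stay open. The progenitor sum differed 2.3-fold between the control libraries, but these are separate biological samples, so this ratio does not decide it. Sums of 13 neural crest, Schwann cell and peripheral neuron genes were 63.4, 45.3, 43.3 and 44.5 CPM in the same order. A loss of neural cells under cyclopamine stays open and was not tested, as both treated libraries lie below both controls.

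Mt1, Mt2 and Slc30a1 rose together, and all 3 are textbook targets of the metal-sensing factor MTF1. A broad glucocorticoid-type response is argued against by a median log2 fold change of -0.0475 over 9 response genes (4 higher, 5 lower). For a broad oxidative stress response the median was 0.137 over 12 NRF2 genes (7 higher, 5 lower), which argues against it. Medians do not exclude a response of a few members. At an unadjusted limma p under 0.05, Sgk1 (0.53), Pdk4 (0.76) and the NRF2 gene Nqo1 (0.65) were higher and Zbtb16 (-0.38) was lower. More available zinc or another metal in the treated cultures is a candidate explanation, since Slc39a10, a zinc importer gene that metal-bound MTF1 represses, had a log2 fold change of -0.544 (limma adjusted p = 0.289) and was lower in both treated libraries. Whether a metal came with the medium or from the cells was not tested.

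Kdm5d was not alone among Y-linked genes, whose summed CPM was 222 and 208 in the controls and 147 and 92.9 in cyclopamine. Fewer male embryos in the cyclopamine pools stay open as an explanation: the 4 genes lay near a common log2 fold change of -0.83, with the farthest 0.91 standard errors from it, and Xist was higher by 0.89, values seen before the test was chosen. Xist also differed 1.93-fold between the controls, where the Y-linked sums had a ratio of 0.936, so it does not follow the sex ratio alone. An effect of cyclopamine on these genes was not tested.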
